A study of Oryza sativa with 4 samples.

How the data were processed

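Poly(A)-selected RNA from developing grain and from roots of rice was sequenced as paired-end libraries, with plants sampled 15 days after panicle emergence. The 4 libraries form 4 groups of 1 library each: Sharbati grain, Lalat grain, Sharbati root and Lalat root. Per the labels, grain iron was 24.88 ppm in Sharbati and 7.80 ppm in Lalat. No group had a replicate.

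Per the submitters' processing notes, reads were handled with Bowtie 0.12.9, TopHat 1.3.3, Cufflinks 1.3.0 and Cuffdiff. The genome build is not given in the sources used here. Expression values are FPKM (fragments scaled to transcript length and sequencing depth) as deposited by the authors, with the grain pair and the root pair processed as separate comparisons. The deposited tables also hold the p-value of the authors' comparison of the 2 libraries of an organ, a log ratio and a yes or no call, which the authors made at a false discovery rate of 0.05. These p-values and calls compare 2 libraries, not 2 cultivars, and are quoted only as the authors' own.

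Each library's table lists only genes above 0 in that library, and the value of the partner library stands beside it. The grain tables together list 38273 transcripts of 28339 genes, and 34828 transcripts of 25225 genes are listed for root. Transcripts of a gene carry the same value, except in 2 genes in each organ, so each distinct value of a gene was taken once and, where 2 values differed, they were summed. The deposited log ratio is headed as a natural logarithm. It lay within 0.001 of the log2 of the FPKM ratio for 31292 of 31307 grain transcripts above 0 in both libraries and for 21434 of 21456 root transcripts, and was used only for this check. In 11 grain genes and 9 root genes the deposited p-value is 1 and the log ratio 0 whatever the FPKM values, so their deposited calls carry no information. In 7 grain transcripts with 8864 FPKM or more in one library, the other library is listed at 0 with such a log ratio of 0. A gene not listed in either table of an organ was treated as absent, not as 0.

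Ratios were computed as log2((a + 1)/(b + 1)) of FPKM, where 1 is the pseudocount. Folds printed as such are plain ratios of the FPKM values. Genes were compared if they were listed in both libraries and reached 1 FPKM in at least 1 of them, and were counted as apart at 2-fold or more. No statistical test was made, because 1 library per group leaves the spread between plants unknown. For groups of genes, the median log2 ratio of members passing the same filter was placed among 10000 random lists of equal size, drawn from 20 bins of mean expression, and given as a percentile from 0 to 100. These percentiles describe the libraries at hand and are not p-values. Lists needed at least 3 members.

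The lists were 14 lists of named genes and 15 lists defined by words in the deposited descriptions. The named lists covered iron regulators, iron storage, iron translocation, phytosiderophore synthesis and iron uptake, NAC regulators of remobilisation, zinc and manganese transport, phytate synthesis and storage, seed storage proteins, starch synthesis, endosperm regulators, embryo and aleurone oil bodies, root transport and root markers, photosynthesis, and reference genes. The word lists covered glutelins, prolamins, the seed allergenic and albumin family, late embryogenesis and oil body proteins, metallothioneins, heat shock proteins, peroxidases, aquaporins, the photosynthetic apparatus, ribosomal proteins, core histones, glutathione S-transferases, ZIP metal transporters, heavy metal domain proteins and germins. Of 122 named entries, 5 were dropped because the deposited description names another kind of gene, 4 of them YSL entries. YSL2, YSL9 and YSL16 are described as transposon proteins in the deposited tables too, but were kept because their deposited terms name iron-nicotianamine transport. Lists of mitochondrially and of plastid encoded products were added after the data had been seen.

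The lists, comparisons, filter, pseudocount and alternatives were fixed before the data were examined, as was the rule for genes named individually. That rule takes up to 4 members of each named list with the largest ratios among members at 5 FPKM or more, the 5 genes with the highest and the 5 with the lowest ratio among informatively described genes at 20 FPKM or more, the reference genes, and for grain every iron gene at 1 FPKM or more. The text gives a selection of the genes this rule names, and 1 further gene of a list is not reported here. Genes named outside this rule are marked as chosen after their values were seen.

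Alternatives were pseudocounts of 0.1 and 5, scaling by the median ratio, scaling to equal totals without the 100 highest genes, absent genes set to 0, the highest transcript only, no filter, a filter of 5 FPKM, a 4-fold threshold and random lists not matched on expression. A filter of 10 FPKM in both libraries, and a Benjamini-Hochberg adjustment over 1 deposited p-value per gene, were added after the data had been seen. The counting and the list procedure were tested on simulated data, where 400 lists without a shift fell outside the middle 95% of random lists in 20, 27, 19 and 19 cases for the 4 comparisons.

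Read totals were not used here, so depth was gauged from the tables. Genes listed at 0 in one library, whose deposited p-value equals the normal probability beyond 1 standard deviation (0.159), were taken to rest on 1 fragment. Their FPKM gives the value of 1 fragment, and its ratio between libraries over shared genes gives the relative depth if FPKM was scaled to mapped fragments. In simulated tables with a 20-fold difference in depth the ratio step returned 20.0, but genes with 1 fragment were known there beforehand. The reading of the p-value as 1 fragment was not simulated. No counting interval could be given for single genes.

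Deposited tables of ontology terms, pathways and unannotated transcripts were planned for description only and were not used here. No column of these tables names a sample, the background of the term lists is not stated, and unannotated transcripts carry identifiers made separately in each table. Transcription factor families were read from the deposited annotation, pooled over libraries. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.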

Results

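RNA abundance was measured in developing grain and in roots of 2 indica rice cultivars, Sharbati and Lalat, 15 days after panicle emergence. Each of the 4 cultivar and organ groups had 1 library, so there are no replicates and every difference below is a difference between 2 libraries. Read totals were not used here. The FPKM value of 1 fragment had a median of 0.0302 in Sharbati grain, 0.0402 in Lalat grain, 0.105 in Lalat root and 1.07 in Sharbati root. By genes shared between libraries, 1 fragment stood for 16.8-fold (through Sharbati grain) or 16.7-fold (through Lalat grain) more FPKM in Sharbati root than in Lalat root. This gap equals the gap in depth if FPKM was scaled to mapped fragments, and in Sharbati root it rests on 5 of 8 and 8 of 14 shared genes that lay within 0.05 log2 of the most frequent ratio.

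Sharbati grain listed 25305 genes, Lalat grain 24886, Lalat root 23740 and Sharbati root 15584. The numbers at 1 FPKM or more were 11218, 12996, 18581 and 13213 in the same order. A few genes took much of the signal in grain: the 10 highest genes held 38.2% of the summed FPKM in Sharbati grain and 29.2% in Lalat grain, against 21.5% in Sharbati root and 8.61% in Lalat root.

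The grain comparison asks which transcripts differ between a cultivar with higher and a cultivar with lower grain iron. The 3 highest ratios belonged to neighbouring prolamin genes, which encode endosperm storage proteins, on chromosome 7 between positions 6609123 and 6613762. PROLM19 (LOC_Os07g11900) stood at 23282 FPKM in the Sharbati library and 4.80 in the Lalat library, PROLM20 (LOC_Os07g11910) at 41724 and 6.42, and PROLM22 (LOC_Os07g11920) at 36617 and 3.03. Of the 18 prolamin loci listed in both libraries, 8 were at least 2-fold higher and 4 at least 2-fold lower in Sharbati grain. Their median log2 ratio was 0.84, at percentile 99.92 of matched random lists. Chosen after their values were seen, PROLM29 (LOC_Os12g17010) was also higher in the Sharbati library, at 36066 against 6969 FPKM, whereas PROLM15 (LOC_Os05g26690) was lower, at 8667 against 41102 FPKM. PROLM3, PROLM6 and LOC_Os05g26400 carry the same values and count as 3 loci.

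A further 5 prolamins had a value in 1 grain library and were listed at 0 in the other. Of these loci, chosen after their values were seen, PROLM4, PROLM14 and PROLM16 reached 16881, 17906 and 17271 FPKM in Sharbati grain, and PROLM25 and PROLM26 reached 13736 and 17132 FPKM in Lalat grain. Missing from both grain tables were 7 glutelins and 5 prolamins, although they stood at 200 FPKM or more in Lalat root, so storage transcripts were only partly listed. The 7 glutelins listed in both grain libraries, which encode the main rice storage protein, had a median log2 ratio of -0.40, at percentile 10.85. Outside this list, and chosen after its values were seen, glutelin GluA2 (LOC_Os10g26060) stood at 12212 FPKM in Lalat grain and was listed at 0 in Sharbati grain. These zeros, of GluA2 and of the 5 prolamins, carry a deposited p-value of 1 and a log ratio of 0, so they do not tell absence from an estimate that failed. Root of the same cultivar listed each of these loci. In Lalat root PROLM4, PROLM14 and PROLM16 stood at 208, 543 and 582 FPKM. In Sharbati root PROLM25, PROLM26 and GluA2 stood at 12.6, 28.8 and 12.1 FPKM. A locus without any transcript in that cultivar is thus argued against, but whether grain lacked them was not tested. Glutelin GluD1 (LOC_Os02g15090) stood at 4879 FPKM in Sharbati and 9549 in Lalat grain, and the 2S albumin SSA1 (LOC_Os05g41970) at 42860 and 26816. The list of 5 seed storage proteins had a median of 0.12, at percentile 59.11, and none of its members was 2-fold apart.

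**Figure D1:**
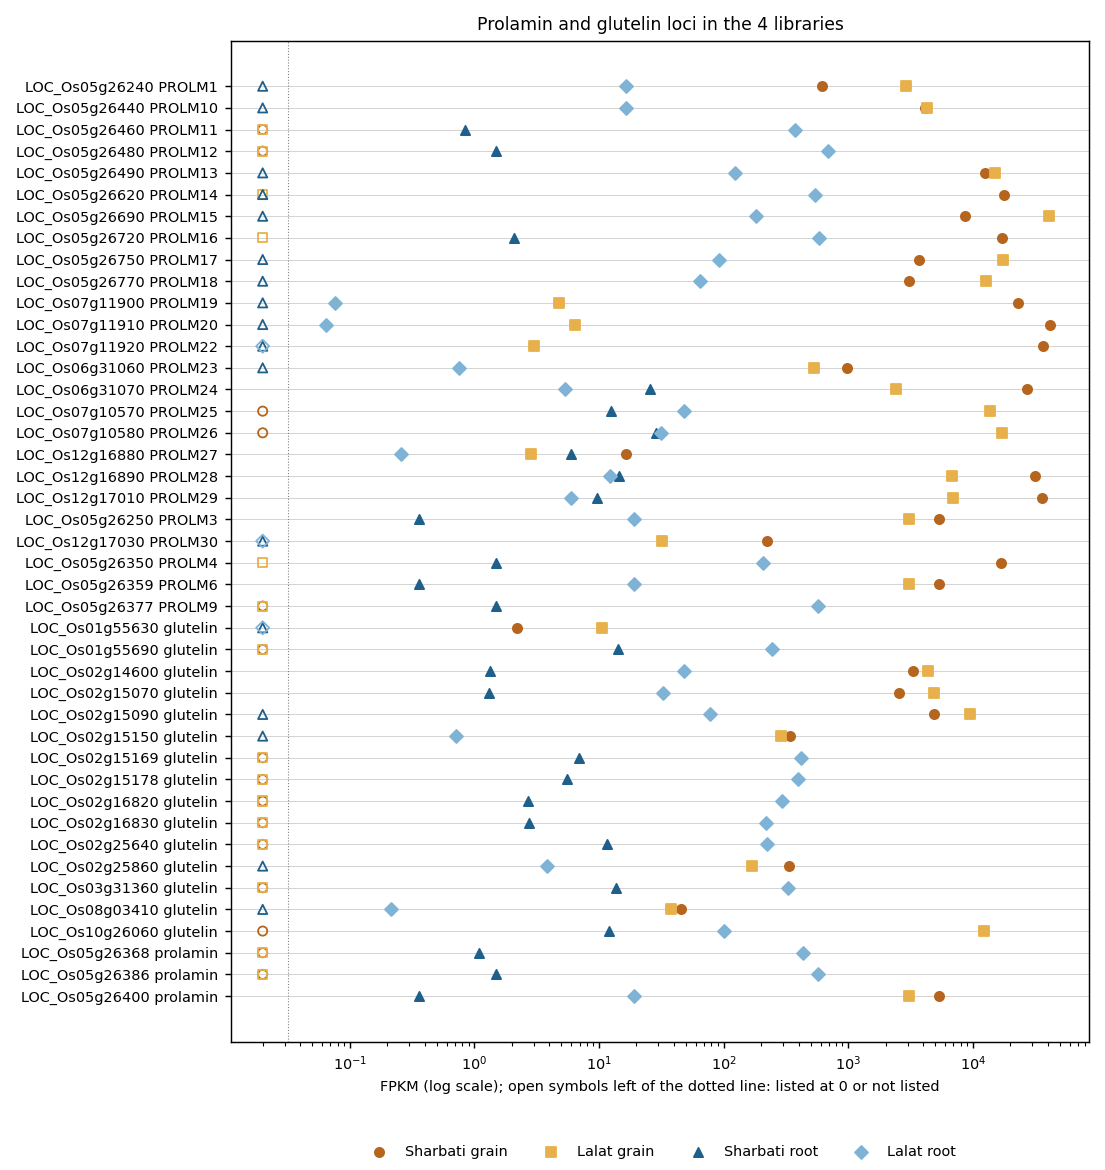
FPKM of every prolamin and glutelin locus (log scale) in the 4 libraries, 1 symbol per library, with open symbols for loci listed at 0 or not listed. PROLM19, PROLM20 and PROLM22 lie between 23282 and 41724 FPKM in Sharbati grain and between 3.03 and 6.42 FPKM in Lalat grain, and 7 glutelins have values in root only.

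Late embryogenesis and oil body proteins, which accumulate as seeds mature, were higher in Sharbati grain: 10 of 35 were at least 2-fold higher and 3 at least 2-fold lower. Their median log2 ratio was 0.59, at percentile 100.0. Among them, chosen after their values were seen, the dehydrins LOC_Os11g26780 and LOC_Os11g26570 stood at 12.4 and 37.1 FPKM in Sharbati grain and at 0.709 and 7.40 FPKM in Lalat grain. The oleosins OLE18 (LOC_Os03g49190) and OLE16 (LOC_Os04g46200), coat proteins of oil bodies and the only members of the oil body list measured in grain, went the other way, with log2 ratios of -1.28 and -1.09. Starch synthesis genes had a median of 0.36, at percentile 91.56, with members on both sides. Soluble starch synthase SSIIIa (LOC_Os08g09230) stood at 227 FPKM in Sharbati and 112 in Lalat grain. Granule-bound starch synthase Wx (LOC_Os06g04200), which makes amylose, stood at 2905 and 8276. The deposited p-value of Wx may stand for a missing one, so the authors' call does not bear on this difference. Whether an estimate failed there was not tested. The endosperm regulators RPBF (LOC_Os02g15350), which binds prolamin promoters, and NF-YB1 (LOC_Os02g49410) stood at 882 against 381 FPKM and at 0.177 against 5.80 FPKM. The median of the 3 endosperm regulators was 0.52, at percentile 87.64.

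Genes of iron handling did not move as a block. The 8 iron regulators had a median log2 ratio of 0.24, at percentile 92.62, and 2 of them were at least 2-fold higher in Sharbati grain. These were PRI1 (LOC_Os08g04390), a bHLH activator of the iron deficiency response, at 35.3 against 10.5 FPKM, and HRZ2 (LOC_Os05g47780), a ubiquitin ligase that restrains that response, at 10.8 against 4.41 FPKM. The regulators IDEF1 (LOC_Os08g01090) and IDEF2 (LOC_Os05g35170) had log2 ratios of -0.60 and -0.95. The iron-nicotianamine transporter YSL2 (LOC_Os02g43370) was higher in Sharbati grain, at 10.8 against 3.17 FPKM, while YSL9 (LOC_Os04g45860) and FRO2 (LOC_Os04g36720), a ferric reductase, had log2 ratios of -0.81 and -1.05. The ferritins FER1 (LOC_Os11g01530) and FER2 (LOC_Os12g01530), which store iron, stood at 1.59 and 0.833 FPKM in Sharbati and at 3.43 and 3.63 FPKM in Lalat grain. The mitochondrial iron importer MIT (LOC_Os03g18550) stood at 2.24 and 4.34 FPKM. Of the phytosiderophore pathway, NAAT1 (LOC_Os02g20360) was at 0.170 against 1.6 FPKM, DMAS1 (LOC_Os03g13390) at 0.404 against 2.73 and NAS2 (LOC_Os03g19420) at 1.49 against 1.71. List medians were -0.77 for iron storage, -0.81 for iron translocation and -1.15 for phytosiderophore synthesis, at percentiles 27.38, 23.29 and 3.90, each over 3 genes.

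**Figure D2:**
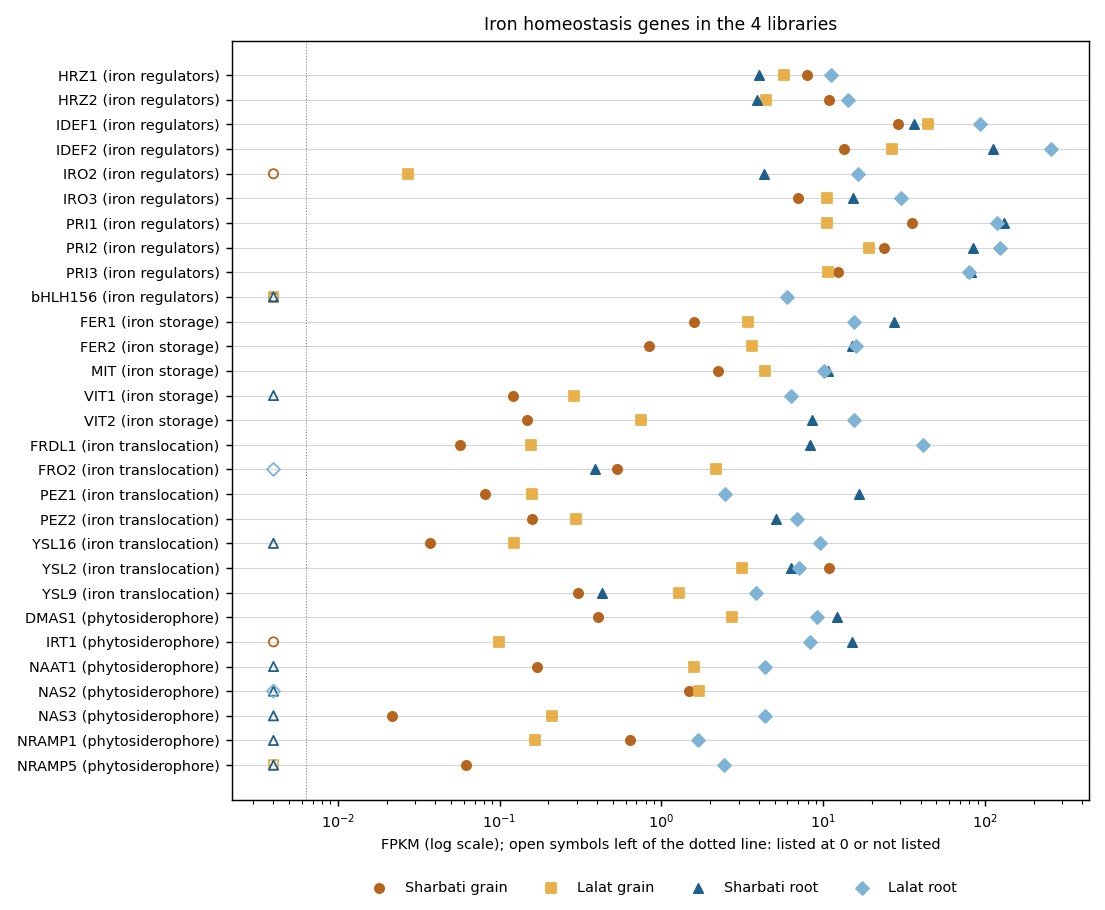
FPKM of iron homeostasis genes (log scale) in the 4 libraries, 1 symbol per library, with open symbols for genes listed at 0 or not listed. PRI1 and YSL2 are higher in Sharbati than in Lalat grain (35.3 against 10.5 and 10.8 against 3.17 FPKM), and FER1 and FER2 are lower (1.59 against 3.43 and 0.833 against 3.63 FPKM).

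The zinc and cadmium transporting ATPase HMA2 (LOC_Os06g48720) stood at 6.95 FPKM in Sharbati grain and 0.0834 in Lalat grain, a log2 ratio of 2.88, with p = 6.1e-08 in the authors' deposited table. In the authors' deposited table NAAT1 (p = 0.00253) and NF-YB1 (p = 6.3e-06) were also called different, whereas YSL2, PRI1, HRZ2, FER1 and FER2 were not. The list of 8 zinc and manganese transporters had a median of -0.16, at percentile 85.18, as deposited and 0.05 after median-ratio scaling. Phytate synthesis genes had a median of -0.02 (0.25 after scaling) at percentile 72.76. Among the other highest ratios were the hevein protein HEV3 (LOC_Os04g09390), at 53.3 against 0.682 FPKM, and an aspartic peptidase (LOC_Os08g09820), at 29.9 against 0.208. The lowest ratios were those of a tetratricopeptide repeat protein (LOC_Os03g06970), at 0.814 against 161 FPKM, a Ser/Thr phosphatase (LOC_Os11g34710), at 0.880 against 131, a core histone domain protein (LOC_Os01g05610), at 1.51 against 86.3, a fasciclin domain protein (LOC_Os09g30010), at 0.635 against 55.0, and a cytochrome P450 (LOC_Os07g33610), at 0.0187 against 23.4.

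Aquaporins, the water channel family, were lower in Sharbati grain: 8 of 14 were at least 2-fold lower and 1 at least 2-fold higher, and their median of -1.06 stood at percentile 0.04. An example chosen after its values were seen is LOC_Os06g22960, at 0.450 against 5.99 FPKM. Ribosomal proteins had a median of -0.23, at percentile 0.72, which became 0.06 after median-ratio scaling and stood at percentile 98.77 when random lists were not matched on expression. Of the 288 ribosomal proteins, 6 were at least 2-fold higher and 35 at least 2-fold lower. The list of plastid encoded products, added after the data had been seen, had a median of -1.04 over 4 genes, at percentile 1.72. Of the 4 genes, 3 were at least 2-fold lower. LOC_Os04g16722 and LOC_Os04g16896 share position and values, so the same measurement counts as separate genes and sets the median. The remaining lists lay within the middle 95% of random lists as deposited. Medians were -0.73 for glutathione S-transferases, -0.73 for ZIP metal transporters, -0.67 for photosynthesis genes, -0.59 for metallothioneins, -0.52 for the photosynthetic apparatus, -0.51 for heavy metal domain proteins (0.32 with a filter of 5 FPKM), -0.38 for the seed allergenic and albumin family (0.44 with a filter of 5 FPKM, then outside that range at percentile 99.77) and -0.37 for peroxidases. Heat shock proteins (-0.22), core histones (-0.10) and reference genes (-0.15) had medians that became 0.04, 0.22 and 0.14 after median-ratio scaling. Germins had fewer than 3 measured members in every comparison, NAC regulators and root markers fewer than 3 in grain. Of the lists fixed beforehand, 4 of 25 lay outside the middle 95% of random lists in grain. For separate lists of unrelated genes 1.25 would, but these are gene families and some share members.

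Of 13417 genes compared in grain, 847 were at least 2-fold higher and 2334 at least 2-fold lower in the Sharbati library, so 26.6% of the genes apart were higher. The median ratio of Sharbati over Lalat was -0.29 on the log2 scale, and scaling that removed this offset gave 1326 higher and 1606 lower genes, 45.2% higher, a balance that centring the ratios brings by construction. Among genes at 10 FPKM or more in both libraries, a filter added after the data had been seen, 262 were higher and 324 lower without scaling. Called different between the 2 libraries in the authors' deposited table were 1102 grain genes, 263 higher and 839 lower in Sharbati.

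**Figure D3:**
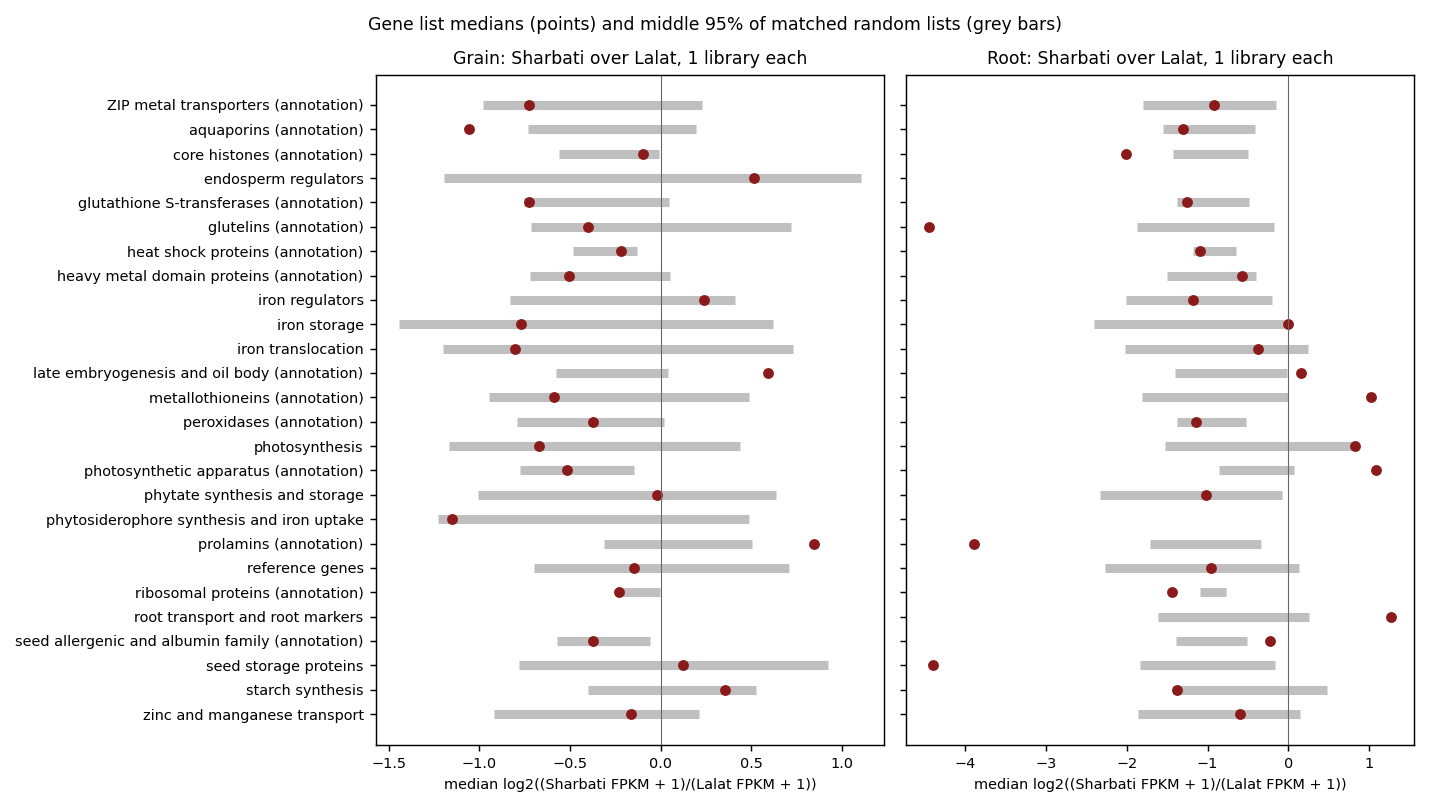
Median log2 ratio of Sharbati over Lalat FPKM for each gene list in grain and root (points, 1 library per cultivar and organ), with the middle 95% of 10000 matched random lists (grey bars). Prolamins (0.84) and late embryogenesis proteins (0.59) lie above the range in grain and aquaporins (-1.06) below it, while seed storage proteins (-4.40) and core histones (-2.01) lie below it in root.

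The root comparison asks the same of the organ that takes up iron. Storage protein transcripts, which belong to the grain, were much higher in the Lalat root library: all 11 seed storage genes measured were at least 2-fold lower in Sharbati root, with a median log2 ratio of -4.40. Glutelins GluB1a (LOC_Os02g15169), GluB1b (LOC_Os02g15178), GluB5 (LOC_Os02g16820) and GluB4 (LOC_Os02g16830) stood at 422, 399, 292 and 217 FPKM in Lalat root and at 6.86, 5.54, 2.68 and 2.74 FPKM in Sharbati root, and were called different in the authors' deposited table. Prolamins PROLM12 (LOC_Os05g26480) and PROLM9 (LOC_Os05g26377) stood at 695 and 578 FPKM in Lalat root and about 1.5 in Sharbati root. The glutelin list had 10 of 10 members lower (median -4.45) and the prolamin list 11 of 16 lower and 2 higher (median -3.90), both at percentile 0.00.

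The highest ratios in Sharbati root belonged to loci annotated with products that mitochondria encode. NADH-ubiquinone oxidoreductase chain 6 (LOC_Os12g34014), a respiratory chain subunit, stood at 493 FPKM in Sharbati and 0.670 in Lalat root, the 49 kDa subunit of that enzyme (LOC_Os12g33958) at 380 and 0.576, mitochondrial ribosomal protein S3 (LOC_Os12g34124) at 290 and 0.0986 and L16 (LOC_Os12g34056) at 244 and 0.175. On a list made after these values were seen, 15 of 15 members were at least 2-fold higher in Sharbati root, with a median log2 ratio of 7.22, at percentile 100.0. Among them 2 pairs share position and values, which leaves 13 distinct measurements, 10 of them in the cluster described next. Of these loci, 14 lie on chromosome 12, and 12 between positions 20452979 and 20679739. In the cluster they ranged from 23.6 to 1435 FPKM in Sharbati root, from 0.0986 to 7.19 in Lalat root and from 0.444 to 6.48 in grain.

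**Figure D4:**
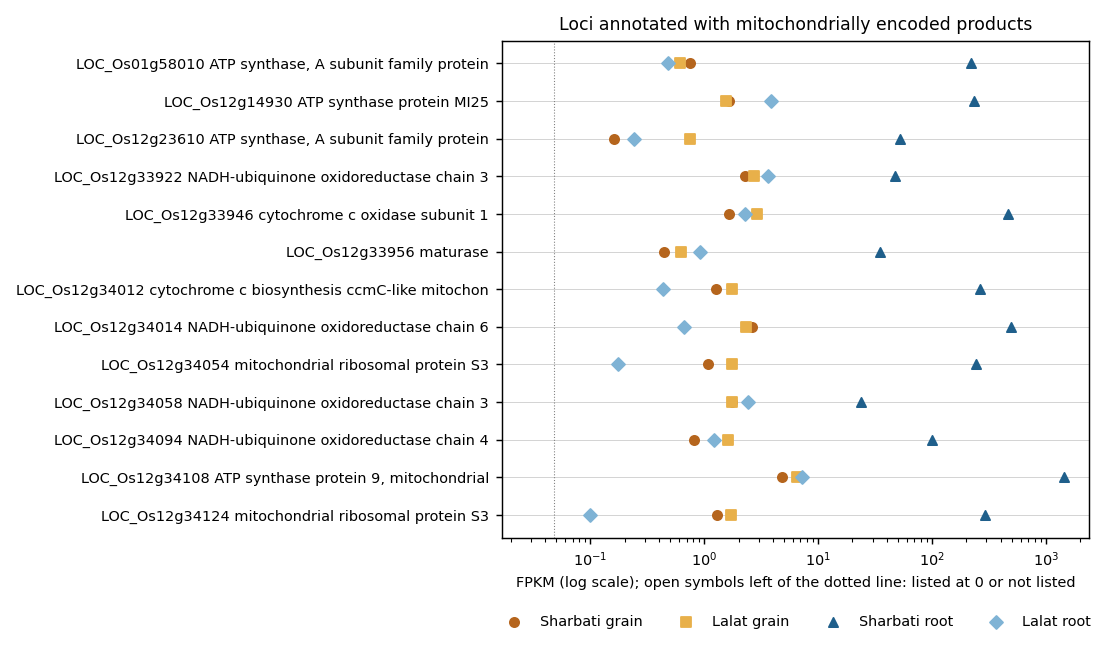
FPKM (log scale) in the 4 libraries of loci annotated with mitochondrially encoded products, 1 symbol per library, with loci that carry the same values drawn once. The 12 loci of the chromosome 12 cluster range from 23.6 to 1435 FPKM in Sharbati root, above the other 3 libraries.

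Root transport genes were higher in Sharbati root as deposited: 4 of 7 were at least 2-fold higher and 1 at least 2-fold lower, with a median of 1.27, at percentile 99.96. Of the 4, HKT2;1 (3.55 FPKM) and PT6 (3.66 FPKM) lie within the 0.293 to 4.52 FPKM that 1 fragment spans in Sharbati root, and the root marker RCc3, at 6.39 FPKM in Lalat root, is left out because it was listed at 0 in Sharbati root. The silicon efflux transporter Lsi2 (LOC_Os03g01700) stood at 115 FPKM in Sharbati and 32.5 in Lalat root, the ammonium transporter AMT1;1 (LOC_Os04g43070) at 31.2 and 10.2, and the silicon channel Lsi1 (LOC_Os02g51110) at 143 and 88.0. Metallothioneins, small metal-binding proteins, had 5 of 9 members at least 2-fold higher and 2 at least 2-fold lower (median 1.03, percentile 100.0). Chosen after their values were seen, LOC_Os05g11320 stood at 320 against 3.47 FPKM and LOC_Os01g74300 at 51.6 against 5057 FPKM. The photosynthetic apparatus list was higher too (median 1.08, 18 of 31 at least 2-fold higher), but its median was -0.32 over the 8 members left by a filter of 5 FPKM, and 10 of its members are also on the list of plastid encoded products. The photosynthesis list of nuclear genes had a median of 0.83, at the upper edge of the middle 95% of random lists. Core histones were lower, 23 of 35 at least 2-fold and 0 higher (median -2.01, percentile 0.01), and so were ribosomal proteins, 180 of 274 (median -1.44, percentile 0.00). After median-ratio scaling the medians of these 2 lists were -1.02 and -0.49. Of all 13653 genes compared in root, 6381 were at least 2-fold lower in Sharbati as deposited.

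The median ratio of Sharbati over Lalat root was -1.0 on the log2 scale over genes at 1 FPKM or more in both libraries. Among iron genes, 5 of 9 regulators were at least 2-fold lower in the Sharbati library. The list's median was -1.18, at percentile 33.63, as deposited and -0.19 after median-ratio scaling. IRO2 (LOC_Os01g72370), a bHLH regulator of phytosiderophore genes, stood at 4.30 FPKM in Sharbati and 16.4 in Lalat root, and HRZ2 at 3.92 and 14.1. The Sharbati root values of IRO2, HRZ2 and, below, ZIP7 lie within the 0.293 to 4.52 FPKM that 1 fragment spans there. Their differences also include the median offset of -1.0. The iron storage list had a median of -0.00 as deposited and 0.94 after median-ratio scaling, at percentile 97.83, with FER1 at 27.3 FPKM in Sharbati and 15.4 in Lalat root and FER2 at 15.0 and 16. Iron translocation had a median of -0.37 (0.50 after scaling) at percentile 84.17, with PEZ1 (LOC_Os03g37490), an exporter of phenolics, at 16.6 against 2.47 FPKM and FRDL1 (LOC_Os03g11734), a citrate transporter, at 8.31 against 41.3. The iron transporter IRT1 (LOC_Os03g46470) and DMAS1 stood at 15.0 against 8.34 and 12.2 against 9.21 FPKM. The zinc transporter ZIP7 (LOC_Os05g10940) stood at 3.44 against 19.8 FPKM and HMA2 at 7.03 against 2.02, in a list with a median of -0.60 (0.41 after scaling). Of these iron and zinc genes none was called in the authors' deposited table for root. Members listed at 0 in Sharbati root are left out of these lists, which favours higher medians. Left out were VIT1 (LOC_Os04g38940) of iron storage, at 6.30 FPKM in Lalat root, and YSL16 (LOC_Os04g45900) of iron translocation, at 9.56. The zinc list lacks ZIP4 (LOC_Os08g10630), at 15.1 FPKM in Lalat root. Among the lowest ratios were a histone H3 gene (LOC_Os05g36280), at 1.70 against 646 FPKM, and a Bet v I family protein (LOC_Os12g36880), at 1.24 against 514 FPKM.

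Medians of the other lists in root were -1.38 for starch synthesis (percentile 3.21), -1.31 for aquaporins (11.96), -1.25 for glutathione S-transferases (8.59), -1.14 for peroxidases (18.05), -1.09 for heat shock proteins (9.30) and -0.92 for ZIP metal transporters (53.15). Phytate synthesis (-1.02), reference genes (-0.96), heavy metal domain proteins (-0.58) and the seed allergenic family (-0.23) had medians of 0.01, 0.09, 0.40 and 0.58 after scaling to equal totals without the 100 highest genes. The seed allergenic family, with 9 of 32 members at least 2-fold higher and 13 at least 2-fold lower, stood at percentile 99.93, and at 96.49 with a filter of 5 FPKM. Late embryogenesis proteins stood at 0.15 and percentile 99.06, but at -0.72 and percentile 73.33 with a filter of 5 FPKM. Endosperm regulators, oil body, NAC and phytosiderophore lists had fewer than 3 measured members in root. Of the lists fixed beforehand, 11 of 24 lay outside the middle 95% of random lists in root. For separate lists of unrelated genes 1.2 would, but these are gene families and some share members. With a filter of 5 FPKM, the iron storage, seed allergenic, late embryogenesis and photosynthetic apparatus lists lay within that range. For iron storage this was only a step across the edge, from percentile 97.83 to 97.49, with the median unchanged.

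Of 13653 genes compared in root, 752 were at least 2-fold higher and 6381 at least 2-fold lower in the Sharbati library, 10.5% higher. Scaling that removed the median offset of -1.0 gave 2423 higher and 2891 lower genes (45.6% higher), while equal totals without the 100 highest genes gave 48.1% higher. Called different in the authors' deposited table were 287 root genes, 69 higher and 218 lower in Sharbati, 103 of them listed at 0 there. At 1 FPKM or more in Lalat root, 5471 genes were listed at 0 in Sharbati root, where 1 fragment stands for 0.293 to 4.52 FPKM from the 10th to the 90th percentile of genes. A gene listed there holds at least 1 fragment, so ratios of genes with low Lalat values have a floor.

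Grain and root of Sharbati were compared to describe organ differences within the cultivar. The tables of the 2 organs were normalized separately, so levels across organs carry that difference. Grain storage genes stood highest over root: PROLM4 (LOC_Os05g26350) at 16881 against 1.5 FPKM, PROLM16 (LOC_Os05g26720) at 17271 against 2.09, and the seed allergenic protein RAL6 (LOC_Os07g11510) at 27669 against 4.70. All 9 prolamins and all 9 starch genes measured were at least 2-fold higher in grain, with medians of 11.95 and 7.18. Root genes went the other way, with Lsi1 at 0.0700 FPKM in grain and 143 in root and a phytosulfokine precursor (LOC_Os12g05260), a growth peptide, at 1.00 and 3907. Medians were -4.74 for root markers, -4.79 for metallothioneins, -3.84 for peroxidases and -2.97 for aquaporins. Iron storage (-3.09, percentile 2.99) and iron translocation (-2.77, percentile 2.61), with 4 genes each, lay within the middle 95% of random lists. FER1 stood at 1.59 FPKM in grain and 27.3 in root, and YSL2 at 10.8 and 6.35. Of 12648 genes, 1771 were at least 2-fold higher and 6455 at least 2-fold lower in grain, 21.5% higher as deposited and 31.6% after an offset of -0.53, the median log2 ratio, was removed.

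The same comparison in Lalat, whose organ tables were also normalized separately, gave smaller ratios for storage genes, which stood higher in Lalat root than in Sharbati root. All 7 glutelins and all 18 prolamins measured were at least 2-fold higher in grain, with medians of 6.91 and 7.58, and starch genes had a median of 6.31 (12 of 15 higher). Glutelin GluA2 (LOC_Os10g26060) stood at 12212 FPKM in grain and 100.2 in root, SSA1 at 26816 and 185, and Wx at 8276 and 17.3. The iron transporter IRT1 stood at 0.0985 FPKM in grain and 8.34 in root, IRO2 at 0.0270 and 16.4, and FRDL1 at 0.157 and 41.3. NAC regulators of nutrient remobilisation had a median of -4.50, with NAC6 (LOC_Os01g66120) at 17.5 against 451 FPKM and NAC5 (LOC_Os11g08210) at 0.217 against 26.5. Core histones were lower in grain (42 of 45 at least 2-fold, median -4.28), as were root markers (-2.99) and peroxidases (-2.86). A jacalin-like lectin (LOC_Os01g24710) had the lowest ratio among named genes, at 0.175 against 2725 FPKM. Of 17533 genes, 1247 were at least 2-fold higher and 10459 at least 2-fold lower in grain, 10.7% higher as deposited, 33.0% after an offset of -1.20, the median log2 ratio, was removed and 39.4% with equal totals without the 100 highest genes.

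The cultivar ratio in grain was set against the cultivar ratio in root over 8011 genes at 1 FPKM or more in all 4 libraries. Among them 545 genes were at least 2-fold apart in the same direction in both organs, where independent ratios would give 513, and 226 in opposite directions, where they would give 207. After median-ratio scaling the numbers were 251 (191 expected) and 244 (195 expected). Across genes, which are not independent replicates, Pearson's r between the 2 ratios was -0.0061.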

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

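The tests reported in this part were all chosen after the results they address had been seen. In 3 genes of the named lists the cultivar ratio was at least 2-fold and had opposite signs in the 2 organs, and this difference between organs was not tested. For OLE18 (LOC_Os03g49190), an oil body coat protein, the log2 ratio of Sharbati over Lalat was -1.28 in grain and 1.43 in root, where the Sharbati value was 2.5 FPKM, within the 0.293 to 4.52 FPKM that 1 fragment spans there from the 10th to the 90th percentile of genes. For HRZ2 (LOC_Os05g47780), a ubiquitin ligase of the iron deficiency response, it was 1.13 in grain and -1.62 in root, where the Sharbati value of 3.92 FPKM lies in that range too and the ratio was -0.78 after median-ratio scaling. For SUS2 (LOC_Os06g09450), a sucrose synthase, it was 1.06 in grain and -3.01 in root. The root ratios of HRZ2 and SUS2 include the median offset of -1.0 between the root libraries, and none of the 3 genes was called in either organ in the authors' deposited table.

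Storage protein transcripts in the Lalat root library were one pattern weighed. All 19 storage genes at 100 FPKM or more in both grain libraries that were listed in Lalat root stood there at a median of 0.563% of their Lalat grain value, with a range from 0.0862% to 2.24%. Carry-over from Sharbati grain is argued against, since the 3 prolamins of chromosome 7 reached 0.0319% of the FPKM that such a share would bring, 0.140 in place of 439.6. Carry-over of Lalat grain RNA at 1 fixed share, and expression in the sampled root tissue itself, cannot be told apart: the log2 ratio of Lalat root over Lalat grain had an SD of 1.11 across genes (95% interval 0.837 to 1.64), and both would list the 19 genes. PROLM3, PROLM6 and LOC_Os05g26400 carry the same values, yet the interval counts them as separate genes. Starch synthesis genes, outside this test, were listed in Lalat root too. Their median log2 ratio of Lalat grain over Lalat root was 6.31, against 6.91 for glutelins and 7.58 for prolamins. Of 15 starch genes, 12 were at least 2-fold higher and 2 at least 2-fold lower in grain. Whether they share 1 percentage with the storage genes was not tested. A cultivar difference in roots remains open and untested.

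The second pattern was the near absence of PROLM19, PROLM20 and PROLM22 from Lalat grain. In the Lalat root table the median of 24 other prolamins, 56.1 FPKM, was 741-fold the highest of these 3, 0.0757. This bears on a failed estimate in the Lalat grain table alone only if storage genes in Lalat root follow those in Lalat grain. Over the 19 storage genes above, the log2 ratio of Lalat root had an SD of 1.11 over Lalat grain and 2.33 over Sharbati grain. Lalat root thus followed Lalat grain more closely than Sharbati grain. The 3 prolamins also have values above 0 in Lalat grain, unlike the zeros that carry a log ratio of 0. A failed estimate in the Lalat grain table alone is therefore argued against, while a failure in both Lalat libraries stays open. Assignment of their reads to other prolamins stays open: the summed FPKM of the other prolamins listed in both grain libraries was 0.825 times as high in Lalat as in Sharbati, but 5 abundant prolamins listed at 0 in 1 library make that sum uninformative. A difference in these loci between the cultivars, or between Lalat and the reference sequence, was not tested and remains open.

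For the third pattern, the mitochondrial-type transcripts in Sharbati root, scatter from low depth is argued against, since the list's median there was 228 times the median value of 1 fragment, and so is a cultivar difference shared by both organs, since the same loci had a median log2 ratio of -0.26 in grain. More organelle RNA or DNA of both kinds may have entered the Sharbati root library, which the plastid loci cannot decide. The 13 distinct plastid loci at 5 FPKM or more had a median of 3.36, at percentile 100.0 of random lists so filtered. Of these, 6 were listed at 0 in Lalat root and taken as 0. All but the highest locus reached 5 FPKM only in Sharbati root, so the filter itself favoured high ratios. Without that filter, 24 distinct plastid loci listed in both root libraries had a median of 1.43, 21 of them at least 2-fold higher, but many lie within the value of 1 fragment in Sharbati root, where being listed sets a floor to the ratio. With loci of the same position and values counted once, the 2 organelle lists held 2.06% of the summed FPKM in Sharbati root and 0.0155% in Lalat root, and without the highest plastid locus (6756 FPKM in Sharbati root) 0.807% and 0.0065%. Whether this came from the plants or from the library preparation was not tested.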

How the results depend on the processing

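The filter of 10 FPKM in both libraries and the Benjamini-Hochberg adjustment were chosen after the results were seen; the other alternatives were planned. Grain and root were compared within each cultivar, and no paired analysis over both cultivars was made. With 1 library per group, no library could be left out. The alternative for unannotated transcripts was not run. Higher and lower below refer to the library named first, and counts are genes at least 2-fold apart unless stated. Where a count differed by more than 1.5 times, the cause was not tested unless given.

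With a pseudocount of 0.1, 3912 grain genes were lower in Sharbati, against 2334. With a pseudocount of 5, which shrinks ratios of weak genes, 400 were higher and 637 lower in grain, 318 higher in root, 3866 lower in Sharbati grain against root, and 777 higher and 6967 lower in Lalat grain against root. Genes apart in both organs then numbered 201 in the same and 119 in opposite directions.

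Median-ratio scaling, which centres the ratios by construction, gave 1326 higher genes in grain, 2423 higher and 2891 lower in root, 3241 higher and 6584 lower in Lalat grain against root, and 251 genes apart in the same direction in both organs. The signs of the ubiquitin gene UBQ5 (LOC_Os01g22490, 0.14) and the zinc transporter MTP1 (LOC_Os05g03780, 0.0175) reversed in Lalat grain against root. Equal totals without the 100 highest genes gave 2567 higher and 2772 lower in root and 3919 higher and 6038 lower in Lalat grain against root. The sign of RINO1 (LOC_Os03g09250, 0.0134) reversed in root, and the signs of UBQ5 (LOC_Os01g22490, 0.36), LPA1 (LOC_Os02g57400, 0.018) and MTP1 (LOC_Os05g03780, 0.23) in Lalat grain against root.

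Absent genes set to 0 gave 1351 higher and 11852 lower in root and 4209 higher in Sharbati grain against root, since more genes were compared. The seed storage list of Lalat grain against root then stood at percentile 0.01, because glutelins missing from the grain tables counted as 0. A filter of 5 FPKM gave 1407 lower in grain and 472 higher in root. A 4-fold threshold gave 155 higher and 294 lower in grain, 220.0 and 2354 in root, 752 and 3425 in Sharbati grain against root, 582 and 5580 in Lalat grain against root, and 39 and 10 genes in the same and in opposite directions in both organs. With 10 FPKM in both libraries, 262 were higher and 324 lower in grain, and 125 and 2012 in root. With random lists not matched on expression, ribosomal proteins in grain stood at percentile 98.77, against 0.72.

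No filter and the highest transcript only left the counts of all 4 comparisons within 1.5 times. With no filter, a pseudocount of 1 keeps genes below 1 FPKM under 2-fold. For the highest transcript, only 2 genes in each organ have transcripts that differ in value. With absent genes set to 0, 24 of 25 grain lists and 19 of 24 root lists stayed on their side of the middle 95% of random lists. So did 18 of 23 lists in Sharbati and 23 of 26 in Lalat grain against root. Scaling moves lists and random lists alike, so percentiles say little about it. The authors' 4 counts of calls all fell under Benjamini-Hochberg adjustment, each by less than 1.5 times, so not every call was kept. The low depth of Sharbati root limits low values there, since 1 fragment stands for 0.293 to 4.52 FPKM from the 10th to the 90th percentile of genes.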

Other observations

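The family summaries and the genes named in this part were chosen after the values were seen. Transcription factor families with 10 or more measured members in grain numbered 21. Of these, 5 had a median above the middle 95% of random lists and 0 below it. For lists of unrelated genes, 1.05 outside would be given. GRAS had a median log2 ratio of 0.38 and bHLH of 0.16. C3H stood at 0.01, bZIP at -0.09 and MYB at -0.04 as deposited, and the last 2 became 0.14 and 0.23 after median-ratio scaling. In root, 1 of 22 families lay above (TALE, 0.14) and 3 below (ERF, -1.43, B3, -1.91, and MYB, -1.31). After median-ratio scaling these medians were 1.13, -0.50, -1.10 and -0.42 in the same order. For lists of unrelated genes, 1.1 outside would be given.

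Of the transcription factors called in grain in the authors' deposited table, the GATA factor LOC_Os05g06340 stood at 11.5 FPKM in Sharbati and 0.686 in Lalat, and the ovule identity gene OsMADS13 (LOC_Os12g10540) at 0.619 and 9.22. Of those called in root in the authors' deposited table, WRKY28 (LOC_Os06g44010) stood at 3.55 and 131 FPKM and WRKY62 (LOC_Os09g25070), a defence regulator, at 6.10 and 133.

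Called in both organs in the authors' deposited table were 37 of 22111 genes listed for both, where 11.7 would be given by independent calls. Of these, 27 had the same direction (7.69 expected), 23 of them lower in Sharbati (7.12 expected). Another 10 had opposite directions (4.02 expected), so both kinds exceeded that number. The expected numbers take no account of expression level, so the excess is not read as a shared cultivar difference. LOC_Os05g47540 and LOC_Os05g47545 carry the same values and count separately. The aquaporin LOC_Os06g22960 was lower in Sharbati in both organs, at 0.450 against 5.99 FPKM in grain and 1.70 against 225 in root. The Bowman-Birk trypsin inhibitor BBTI5 (LOC_Os01g03360) was higher in Sharbati grain, at 41.0 against 0.961 FPKM, and lower in Sharbati root, at 13.1 against 403.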
